A study of Danio rerio with 6 samples.

How the data were processed

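The samples were cells of larval zebrafish, sorted as olfactory sensory neurons by green fluorescence from dissociated heads, and the measurement was poly(A)-selected RNA sequencing of 3 control and 3 gallein samples. The sort relied on a transgenic line in which the promoter of OMP, a gene of mature olfactory neurons, drives a fluorescent calcium sensor through Gal4 and UAS. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase and turned into libraries with a kit that amplifies complementary DNA by single-primer isothermal amplification.

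The authors deposited whole-number read counts per gene, 2 files for each of the 6 samples. Per the submitters' processing notes, TopHat2 2.0.4 and HTSeq were used with the zebrafish build Zv9. The annotation release, the counting mode and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. Odorant receptor genes lie in a large family of similar sequences, and values of single receptor genes are uncertain where reads were shared or dropped as not unique.

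Each file held 32469 gene rows, 92 rows of ERCC spike-in RNA (synthetic control transcripts) and 5 rows that name no gene. The sources used here do not say what the 2 files of a sample are. They differed by little more than sampling noise, with a chi-square per gene of 1.37 to 1.76 within a sample against 426 to 1621 between replicates of 1 group, so they were summed and counted as 1 replicate. Rows that name no gene held between 19.4% and 33.9% of each sample's total, and the largest of them, alignments that were not unique, reached 22.3% in gallein replicate 2. These rows and the spike-in rows stayed out of library sizes and of the main tests. Gene counts per sample then ranged from 30822664 to 40295728. Counts of a sequenced library are not independent molecules, so a bound drawn from a count of 0 covers counting error only.

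Gene symbols came from a table that named 20734 of the 32469 gene identifiers. Part of its symbols are capital names of the kind used for orthologues in other species, without the letter that tells zebrafish duplicates apart, and the same symbol can stand for several genes. A listed symbol was matched without regard to case, and a capital symbol also matched the listed name without its final a or b. That matching rule was set after the symbol table had been seen. No coordinates are given, because no annotation of the build was used here.

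Gene counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter with its minimum count of 10, a robust quasi-likelihood fit with group as the only term, and Benjamini-Hochberg adjustment over the 18271 genes that passed the filter. The threshold was an adjusted p of 0.05, two-sided. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Levels are TMM-scaled CPM (counts per 1000000 counts), given as mean ± SD over 3 samples.

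The design, the tests, the alternatives and 39 gene lists were fixed before the data were examined. Lists with at least 3 tested members (37 of the 39) were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry. Camera compares a list with all other genes tested, and fry asks whether the members of a list move on balance in 1 direction. The named genes followed a rule: genes past the threshold whose gallein and control samples did not overlap, then up to 4 members of each list with the smallest p (10 for the odorant receptors), then 5 markers of the sorted cells. The rule's opening part named 0 genes, and the text names a selection from the rest.

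Values with 1 number per sample were compared by exact permutation tests, two-sided. With 3 samples against 3 the smallest p these tests can give is 0.1. Odorant receptor genes were called detected at 5 or more counts after every sample had been thinned at random to 30822664 gene counts. The floor used for a group without counts was 3 counts over the group, set against the TMM-scaled total of its libraries.

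The steps were tested on simulated data with known answers. In counts drawn with the real means, library sizes and dispersions (17229 genes in the fit), 0% of 100 genes changed 4-fold and 5% of 100 genes changed 16-fold were recovered in the gallein against control layout, with 0 false calls. With the dispersion lowered to 0.05 (18128 genes in the fit), 100% were recovered at either fold, with 9 false calls among 209.

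The alternatives were other scaling factors (upper quartile, the size factors of DESeq2 1.42.0, spike-in totals, library size only), other filters on low counts, the replicate number as a block, 1 factor of unwanted variation from control genes or from spike-ins, each file of a sample alone, the DESeq2 Wald test, limma-voom, and each replicate left out in turn. A ribosomal protein list without S6 kinase genes was added after seeing the data.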

Results

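RNA was measured in cells sorted as olfactory sensory neurons from the heads of zebrafish larvae at 5 days post fertilization. They also held RNA of other tissues: the mean log2(CPM + 1) in the controls was 5.30, 5.60 and 5.62 for lens, skeletal muscle and skin genes, 3.17 for brain, 1.82 for erythroid and 1.62 for myeloid genes, and 3.07 for genes of mature ciliated olfactory neurons. Such means over different genes do not rank the shares of tissues. Treatment began at 16 to 20 hours post fertilization with 100 µM gallein, a small molecule that inhibits signalling by the beta-gamma dimer of G proteins, or with the solvent DMSO as control, with fresh medium every 24 hours. Each group held 3 samples, which the labels call biological replicates. Gene counts were 38030353, 40295728 and 34845638 in control replicates 1 to 3 and 38101548, 32492455 and 30822664 in gallein replicates 1 to 3.

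The comparison of gallein with control addressed the expression of odorant receptor (OR) genes, a family of receptors through which olfactory neurons detect odorants. OR transcripts had lower mean levels in the gallein samples. Fewer OR genes were detected in every gallein sample (33, 11 and 35 of 93) than in any control sample (47, 50 and 45). Transcripts of the odorant transduction cascade and of OlfC receptors also had lower mean levels, while those of ribosomal proteins and of nuclear-encoded respiratory chain subunits had higher ones. No single gene passed the threshold in edgeR, and no list kept its call with an estimated inter-gene correlation. Without gallein replicate 2 the medians of the last 2 lists were 0.28 and 0.06, and neither was called.

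Of the 39 OR genes with enough counts for the test, 29 had a negative and 10 a positive log2 fold change, with a median of -1.04. By edgeR, 0 of them rose and 0 fell, over all genes tested as well as adjusted over the list alone. In 8 OR genes all 3 gallein samples lay below all 3 controls, and in 0 they lay above. Among all 18271 genes tested these counts were 954 and 697. The OR genes varied together (estimated inter-gene correlation 0.273), so the 8 are not independent results. Camera placed the family below the other genes (Benjamini-Hochberg adjusted p = 2.70e-08 with the preset correlation, adjusted p = 0.767 with an estimated correlation), and fry gave an adjusted p of 0.595. The preset-correlation p was under 0.05 without each library in turn, and the median was -0.64 without gallein replicate 2, -1.86 without gallein replicate 1 and -1.82 without gallein replicate 3. The preset call was lost with at least 10 counts in every sample, where 4 OR genes were tested (adjusted p = 0.0924), and with 1 factor of unwanted variation from spike-ins (adjusted p = 0.0876). Under spike-in size factors the median of all genes tested was -1.67, against 0.07 with TMM factors, -0.07 with upper-quartile factors and -0.49 with library size only. The OR median lay below the median of all genes by these scalings, at -0.77 relative to it with spike-in factors and -1.11 with TMM factors.

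The largest differences among OR genes by p were those of or70a12, or90a1 and or55e1. No read of or70a12 (ENSDARG00000018521) was counted in any gallein sample, against 182 counts over the controls. That puts it at least 35.96-fold lower, a bound that covers counting error only and not the spread between libraries. Most of the control counts came from control replicate 1, with 121, 36 and 25 in control replicates 1 to 3. The level of or90a1 (ENSDARG00000070341) was 6.86 ± 10.5 CPM in controls and 0.0725 ± 0.103 CPM in gallein (SD, n = 3), and control replicate 1 alone stood at 19.0 CPM. For or55e1 (ENSDARG00000077211) the levels were 0.778 ± 0.576 and 0.0271 ± 0.047 CPM. The edgeR log2 fold change of or90a1 was -6.49 ± 1.87 (SE, adjusted p = 0.756, Benjamini-Hochberg), and that of or55e1 was -4.51 ± 1.70 with the same adjusted p. For or70a12 it was -8.73 ± 2.15, also with that adjusted p. The DESeq2 Wald test called or90a1 (adjusted p = 0.00471) and or70a12 (adjusted p = 0.0130) lower. Of the other OR genes named by the rule, or62c5, or11.17, or90d1, or93a7 and or42e1 had gallein samples all below the controls, with log2 fold changes between -2.91 and -3.64. For or42c5 (-1.73) and or62a2 (-2.55) the samples overlapped. The most steady of these in controls was or90d1, at 1.82 ± 0.204 CPM against 0.136 ± 0.235 CPM.

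Summed over the 93 OR genes, expression was 138, 72.7 and 99.1 CPM in the controls and 103, 10.9 and 79.6 CPM in gallein. The log2 fold change, taken between the means of the log2 levels, was -1.16 (exact permutation p = 0.5, two-sided, n = 3 per group), a difference within the spread between replicates. Without gallein replicate 2 it was -0.14. The number of OR genes detected at equal depth was 47.3 ± 2.52 in controls and 26.3 ± 13.3 in gallein (exact permutation p = 0.1, the smallest this design allows). It was lower in 3 of 3 gallein samples, and adjusted over 13 such comparisons the p was 0.26. Without gallein replicate 2 the difference was -13.3 genes, against -21 with it.

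**Figure D1:**
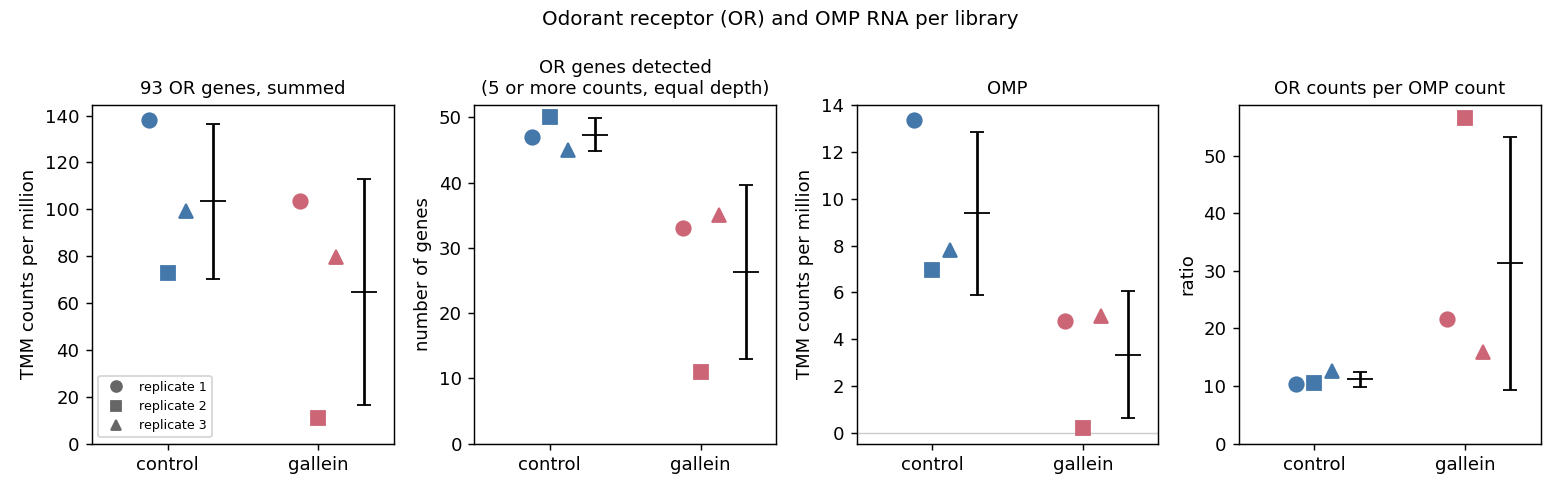
Summed expression of 93 OR genes and expression of OMP in TMM-scaled CPM, OR genes detected (5 or more counts at equal depth) and OR counts per OMP count, for each library of both groups, with the bar giving mean ± SD (n = 3). OR genes detected were 11 to 35 in gallein and 45 to 50 in control libraries, and gallein replicate 2 lies farthest from the rest.

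Transcripts of mature ciliated olfactory neurons, the odorant transduction cascade among them, had a median log2 fold change of -1.09 over 23 tested genes, 20 of them negative and 0 past the threshold. Camera's adjusted p was 0.000400 with the preset and 0.767 with an estimated correlation. The preset call was lost with at least 10 counts in every sample (median -0.48, adjusted p = 0.0694) and with 1 factor from spike-ins (-0.51, adjusted p = 0.537), and the median was -0.65 without control replicate 2 and -0.70 without control replicate 3. OMP, the marker behind the sort, stood at 9.38 ± 3.48 CPM in controls and 3.33 ± 2.72 CPM in gallein, with a log2 fold change of -1.49 ± 1.04 (SE, edgeR adjusted p = 0.822), and gallein replicate 2 held only 4 OMP counts. The log2 fold changes were -1.09 for gnal, the G protein alpha subunit coupled to ORs, -1.14 for cnga4 and -2.16 for cngb1b, subunits of the olfactory cyclic nucleotide-gated channel. Of the 2 genes named ADCY3, the adenylyl cyclase of the cascade, ENSDARG00000017437 had -1.82 and ENSDARG00000077145 had -0.57. The list also took in, under a zebrafish name, genes named CNGA3, which is known as a channel subunit of cone photoreceptors. They were at -4.15 (ENSDARG00000012297) and -2.50 (ENSDARG00000070726), and for the latter the groups overlapped. The value of GNG13, a gamma subunit of olfactory neurons, was -2.52 and rested on control replicate 3 (2158 CPM against 86.7 to 198 CPM elsewhere). Without that library it was 0.05.

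Counted against OMP in the same library, OR transcripts were not lower in gallein. There were 10.3, 10.5 and 12.7 OR counts per OMP count in the controls and 21.6, 56.5 and 16.0 in gallein, higher in 3 of 3 samples (exact permutation p = 0.1, 0.26 adjusted over 13 comparisons). Per gnal count the log2 ratio differed by -0.07 (exact permutation p = 0.9), and per cnga4 count by 1.43 (exact permutation p = 0.2). The cnga4 value rested on gallein replicate 2, at 113 OR counts per cnga4 count from only 2 cnga4 counts, where gnal held 51 counts. Gallein replicates 1 and 3 were at 15.6 and 10.3, and the controls between 7.43 and 13.1.

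OlfC receptors, the receptor family of microvillous olfactory neurons, had a median of -2.70 over 9 tested genes, 7 of them negative, and 0 passed the threshold. Camera's adjusted p was 0.000146 with the preset and 0.627 with an estimated correlation, and the median was -1.62 without control replicate 1. The level of olfcq12 was 1.47 ± 0.38 CPM in controls and 0.131 ± 0.082 CPM in gallein, and that of olfcv3 was 2.15 ± 0.737 and 0.143 ± 0.186 CPM, with all gallein samples below all controls for either gene. Trace amine-associated receptors, another family of ciliated neurons, summed to 4.58 ± 1.57 CPM in controls and 4.07 ± 3.59 CPM in gallein (exact permutation p = 0.6). The 2 ORA genes, a small receptor family, together held 54, 11 and 31 counts in the controls and 1, 0 and 0 in gallein (exact permutation p = 0.1). Across the 4 receptor families the smallest adjusted p of the summed levels was 0.4. Other transcripts of microvillous and crypt neurons had a median of -0.09 over 14 genes (adjusted p = 0.384, camera), and of -0.61 in limma-voom. Their mean log2(CPM + 1) was 3.73, 3.77 and 4.04 in the gallein libraries and 4.26, 4.16 and 4.37 in the controls, with an unadjusted fry p of 0.0449 (0.50 adjusted).

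G protein beta and gamma subunits, the family gallein acts on, had a median of -0.25 over 15 tested genes, 11 of them negative (camera adjusted p = 0.644). Their smallest p belonged to GNG7, with a log2 fold change of -1.77 ± 0.84 (SE, edgeR adjusted p = 0.778). GNG7 was at 15.8, 11.1 and 46.1 CPM in control replicates 1 to 3 and at 7.08, 2.65 and 11.7 CPM in gallein, so the groups overlapped. Effectors of the dimer had a median of -0.06 and a mean of 0.21 over 14 genes (camera adjusted p = 0.621), and camera's direction for them was down. KCNJ3, a potassium channel opened by beta-gamma, was at 687 CPM in gallein replicate 2, 29.0 in replicate 3 and 0.951 in replicate 1, against 5.38 ± 0.559 CPM in controls. Transcription factors and chromatin genes tied to receptor choice had a median of -0.28 over 28 genes (camera adjusted p = 0.423). Among them lhx2a, which encodes a LIM homeodomain factor, was at 7.49 ± 8.85 CPM in controls and 0.625 ± 0.797 CPM in gallein. The value of setdb1a, a histone methyltransferase gene (4.90), rested on gallein replicate 3, and was -0.22 without it. Intraflagellar transport and BBSome genes, which build and maintain cilia, had a median of -0.45 over 20 genes, 15 of them negative (camera adjusted p = 0.0433 with the preset, 0.767 with an estimated correlation). The preset call was lost without 5 of the 6 libraries in turn (adjusted p from 0.0676 to 0.309), in the DESeq2 fit (0.0700) and with 1 factor from spike-ins (0.106). IFT140 was at 10.1 ± 2.25 CPM in controls and 4.27 ± 1.43 CPM in gallein. For BBS7 (-1.94) control replicate 2 stood at 38.7 CPM and the other 5 libraries between 4.13 and 6.55 CPM.

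Ribosomal protein genes had a median log2 fold change of 1.21 over 80 tested genes, 68 of them positive (camera adjusted p = 1.03e-06 with the preset, 0.838 with an estimated correlation). Without gallein replicate 2 the median was 0.28 and the preset call was lost (adjusted p = 0.396). The list's name pattern had also caught 10 S6 kinase genes, among them RPS6KL1 (-2.60), and without them the median was 1.25 over 70 genes. RPS14 was at 382 ± 170 CPM in controls and 1793 ± 880 CPM in gallein, with all gallein samples above the controls. RPL35A was at 525 and 476 CPM in gallein replicates 1 and 2 and at 24.6 CPM in replicate 3, within the control range. Nuclear-encoded respiratory chain genes had a median of 0.60 over 79 genes, 58 of them positive (camera adjusted p = 0.00376 with the preset, 0.878 with an estimated correlation). The preset call was lost without gallein replicate 2 (median 0.06, adjusted p = 0.808), control replicate 3 (0.38, adjusted p = 0.158) or gallein replicate 1 (0.48, adjusted p = 0.0839). Their leading members were uneven between libraries: cox8a was higher in gallein replicates 2 and 3, at 430 and 341 CPM, and NDUFB7 in replicate 1, at 277 CPM. With 1 factor of unwanted variation from spike-ins, a fit in which the median of all genes was 0.000246, preset-correlation camera called both lists lower, at -0.91 for ribosomal proteins (adjusted p = 0.000508) and -0.67 for the respiratory chain (adjusted p = 0.00412). With 1 factor from control genes neither was called (adjusted p = 0.0536 and 0.417). The factor from spike-ins partly followed the groups, at -0.0428, 0.497 and 0.406 in control replicates 1 to 3 and -0.313, -0.685 and 0.139 in gallein replicates 1 to 3. Fitting it can therefore take out part of the treatment difference. Transcripts of the mitochondrial genome took 31.7% to 40.3% of gene counts in the controls and 40.5%, 8.86% and 36.9% in gallein.

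Immediate early genes, which respond to activity and to cell dissociation, had a median of 0.59 over 32 genes, 25 of them positive (camera adjusted p = 0.0129 with the preset, 0.767 with an estimated correlation). The preset call was lost in 8 of 19 alternatives, among them without control replicate 2 (median 0.36, adjusted p = 0.254). NR4A2 was at 57.9 CPM in gallein replicate 3, where the other gallein libraries were at 9.40 and 5.49 CPM. EGR3 was at 61.7 CPM in gallein replicate 1. Heat shock genes had a median of -0.92 over 20 genes (camera adjusted p = 0.0712), led by HSPH1, whose control mean of 206 ± 346 CPM came from replicate 3. Without that library the list median was -0.12 (adjusted p = 0.703), while 6 of 19 alternatives called the list with the preset, among them DESeq2 (0.00953) and the fit without control replicate 1 (0.0141). Cell cycle genes had a median of 0.28 over 32 genes (camera adjusted p = 0.0659). It was 0.02 without gallein replicate 2 and -0.03 without gallein replicate 1, while 5 of 19 alternatives called the list with the preset, among them limma-voom (0.0355) and the fits without control replicate 1 (median 0.72, adjusted p = 0.00146) and without gallein replicate 3 (0.57, adjusted p = 0.00332). In the main fit the adjusted p with an estimated correlation was 0.767 for heat shock and 0.866 for cell cycle genes. The mitotic kinase genes aurka and plk1 lay above all controls in all 3 gallein samples, plk1 at 101 ± 87.7 CPM against 22.1 ± 8.69 CPM. In the antioxidant list (median -0.13, mean 0.07, camera adjusted p = 0.975), the ferritin gene fth1a was at 15105 CPM in gallein replicate 1 against 202 ± 117 CPM in controls. The remaining state lists had medians of 0.34 for progenitors and immature neurons, -0.21 for synaptic vesicles, -0.37 for the circadian clock, -0.10 for cholesterol synthesis, 0.09 for the unfolded protein response, 0.10 for apoptosis, 0.15 for aryl hydrocarbon receptor targets, -0.16 for motile cilia and 0.30 for the mitochondrial genome. Their camera adjusted p ranged from 0.0826 to 0.965, and single libraries moved these medians widely: with 1 left out they ran from -0.12 to 0.61 for progenitors, from -0.62 to 0.28 for synaptic vesicles and from -0.67 to -0.12 for the circadian clock. Median or mean and camera's direction differed in sign for synaptic vesicles (mean 0.10, direction down), aryl hydrocarbon receptor targets (down), the antioxidant list (up) and apoptosis (down).

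Markers of other cell types, and of liver and yolk as RNA of other tissue, had list medians of either sign. Median log2 fold changes were 1.54 for erythroid genes, 1.21 for pigment and neural crest, 1.13 for myeloid and leukocyte genes, 0.49 for lens, -0.90 for photoreceptors and -1.72 for liver and yolk genes. Camera's adjusted p for these 6 lists lay between 9.88e-07 and 0.0332 with the preset and between 0.767 and 0.838 with an estimated correlation. TYRP1, an enzyme gene of pigment cells, was at 20418 CPM in gallein replicate 2 against 21.5 ± 9.76 CPM in controls, and its log2 fold change of 8.31 became -0.96 without that library. The embryonic globin gene hbae1.1 (3.78) likewise became -0.05. Without gallein replicate 2 the erythroid median was -0.02 and the pigment median -0.26, and without control replicate 2 the photoreceptor median was 0.11. Without gallein replicate 1 the lens median was 0.02 (adjusted p = 0.550), and without control replicate 1 the liver and yolk median was -0.96 (adjusted p = 0.00259). The preset call was lost in 8 of 19 alternatives for erythroid and for myeloid genes, in 6 for lens, in 4 for pigment, in 2 for photoreceptor and in 0 for liver and yolk genes. Other leading members were gata1a, MMP9, rac2, pmela and crybb1l2 with higher mean levels in gallein, and rcvrna, APOB and CP with lower ones. CRYBA1, a lens crystallin gene, was at 103 CPM in gallein replicate 1 and below 2 CPM in the other 5 libraries. The remaining lists had medians of 0.09 for skin, 0.06 for skeletal muscle, 0.39 for brain neurons and glia, 0.62 for cartilage, 0.17 for endothelium, 0.17 for hair cells (camera's direction down), -0.31 for olfactory support cells and 0.36 for terminal nerve neurons, with camera adjusted p from 0.135 to 0.965. The cartilage median was -0.60 without gallein replicate 2 (direction down, adjusted p = 0.0904) and 0.996 without gallein replicate 1, where camera with the preset called the list (adjusted p = 0.00342; in the main fit adjusted p = 0.878 with an estimated correlation). Of the 24 lists without a call in the main fit, 19 had a median of the other sign without at least 1 of the libraries, and 5 were called in at least 1 alternative (heat shock, cell cycle, circadian clock, skeletal muscle and cartilage).

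**Figure D2:**
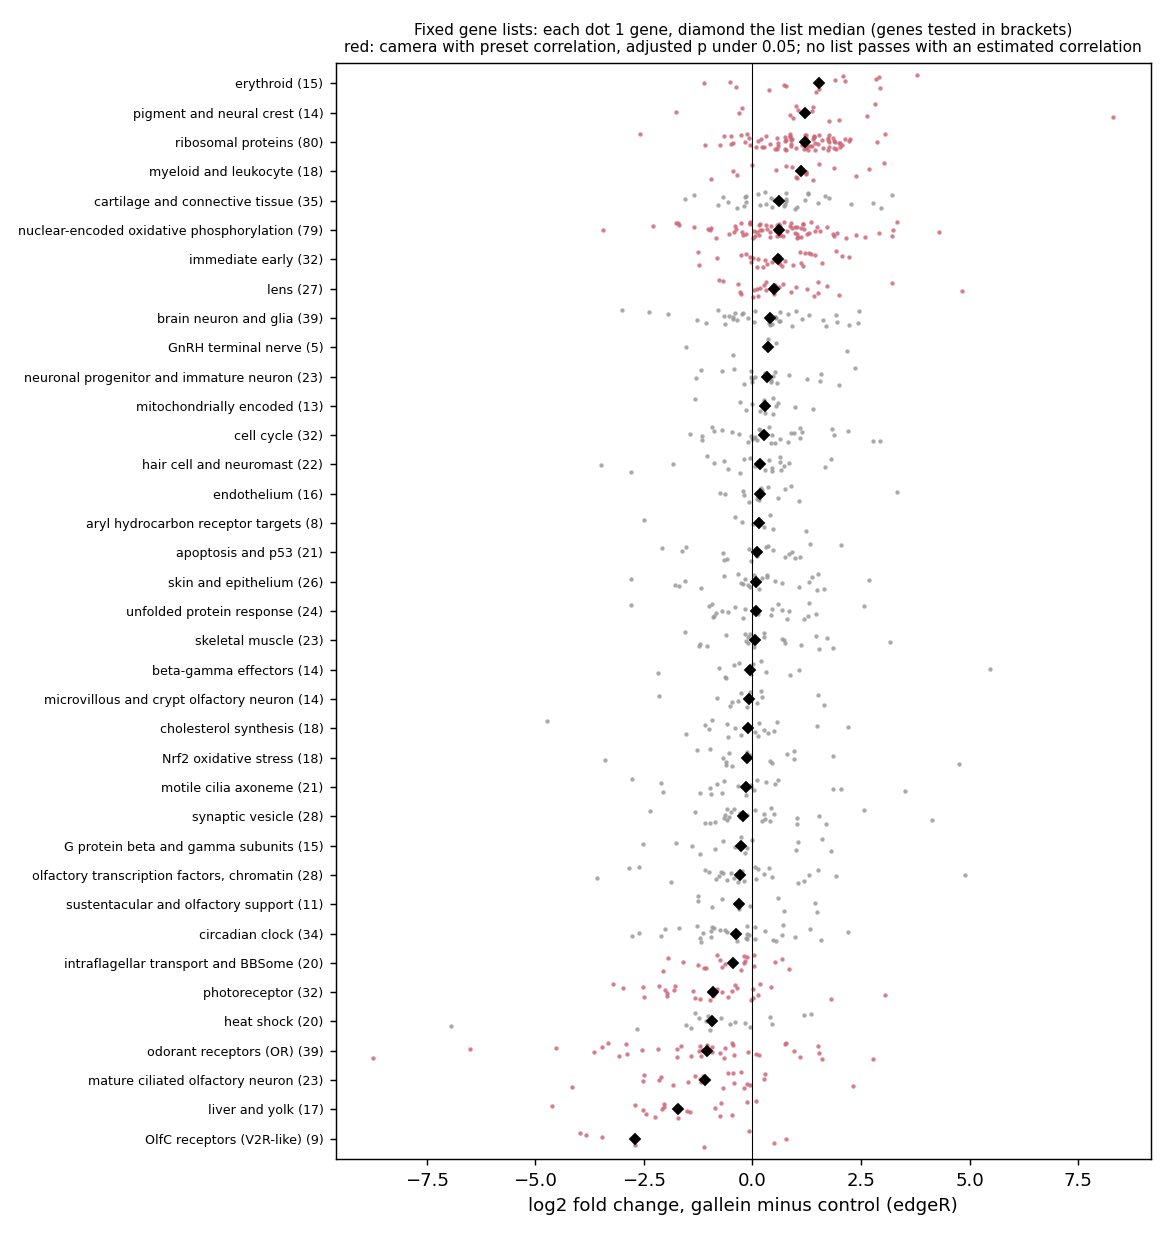
The edgeR log2 fold changes (gallein minus control, horizontal axis) of the tested members of 37 gene lists, 1 dot per gene and a diamond at each list's median, with red dots for the 13 lists called by camera with its preset correlation. With an estimated correlation 0 lists were called.

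Over all 18271 genes tested, edgeR called 0 genes (smallest Benjamini-Hochberg adjusted p = 0.756), with 1187 genes at an unadjusted p under 0.05 where chance gives 914. Of the 9 other splits of the 6 libraries, each an uneven mix of the groups, 6 gave more such genes (1210 to 2601). limma-voom also called 0 genes, with 524 at an unadjusted p under 0.05, and the DESeq2 Wald test called 93, of which 54 rose and 39 fell. All 3 gallein samples lay above all controls in 697 genes and below them in 954, together 9.04% of genes, where chance gives 10%. The common dispersion was 0.802, a coefficient of variation of 0.895 between samples of 1 group. That value pools both groups, and the gallein samples were less alike than the controls. Rank (Spearman) correlations between libraries were 0.659 to 0.724 within gallein, 0.785 to 0.837 within control and 0.689 to 0.812 between the groups. Spike-in RNAs with a mean count of 1000 or more had a median dispersion of 0.0897, against 0.787 for genes of like mean count, and those with 10 to 100 counts had 1.27 against 0.678.

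**Figure D3:**
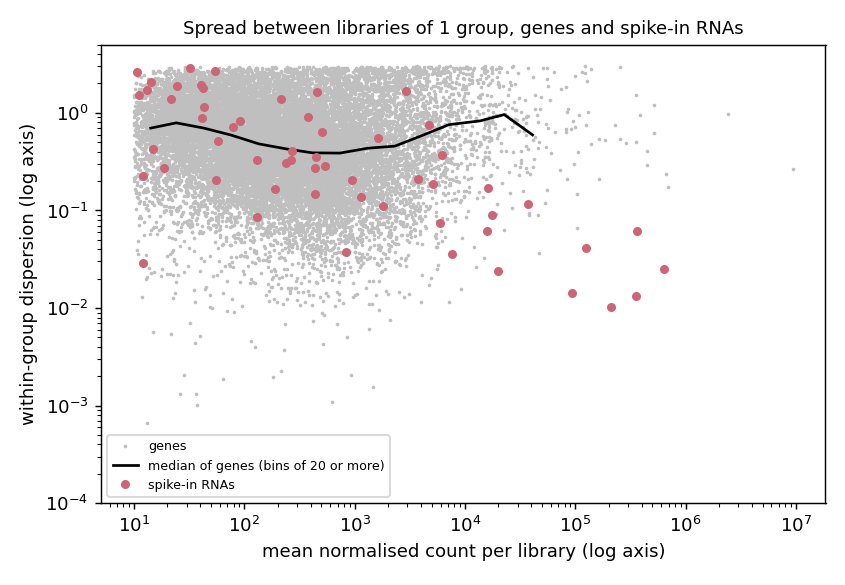
Within-group dispersion (vertical log axis) against mean normalised count per library (horizontal log axis) of genes (grey), their binned median (line) and spike-in RNAs (red). At 1000 counts or more most spike-ins lie below the gene median, and at 10 to 100 counts most lie above it.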

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

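The tests of the spike-in share, of the odorant receptor (OR) ratio, of the neuron list and of gallein replicate 2 were chosen after the results had been seen, while those of dispersion, cell makeup and other splits were set down before theirs.

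The spike-in RNA rows, which lie outside the gene measurement, took 7.68% of assigned reads on average in the gallein libraries (8.14%, 9.21% and 5.69%) and 3.64% in the controls (4.53%, 2.24% and 4.15%), higher in 3 of 3 samples (exact permutation p = 0.1, 0.26 adjusted over 13 comparisons). If the same amount was added to each sample, less cellular RNA in the gallein samples is a candidate explanation, and genes detected at equal depth went with it, at -1688 on average (exact permutation p = 0.2). More spike-in RNA in the gallein samples could give the same share, and the same difference, -1.75 pooled SD, lay too near the spread to exclude it. The sources used here give no cell numbers or spike-in amounts, and an effect of gallein on the number or RNA content of sorted cells remains untested.

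The OR family's lower level may come from fewer olfactory neurons, or less of their RNA, among the sorted cells, and the median of -1.09 for the list of ciliated neuron genes, which holds no receptor, goes with that, although its call was lost with an estimated correlation (adjusted p = 0.767) and in 2 of 19 alternatives. In mean log2 level some lists of other cell types differed as much or more, with photoreceptor genes at -0.743, pigment genes at 0.773 and liver and yolk genes at -1.50 against -0.753 for the neuron list, but relative to their spread they differed less (-0.73 and 0.68 pooled SD against -2.26, with 12 of 13 lists under 1, and -1.31 for liver and yolk genes, which the design did not count among the 13). Some lists that mark no cell type also differed by more than 1 pooled SD, such as intraflagellar transport and BBSome (-2.73), cholesterol synthesis (-1.83) and immediate early genes (1.55). Others, such as the unfolded protein response (-0.09), did not. Gallein replicate 2 as the only source was excluded for the number of OR genes detected, which stayed lower by 13.3 on average without it (value -13.3), but the summed OR level rested on that library, with a log2 fold change of -0.14 without it. A change of OR transcripts relative to other RNA of the same neurons could not be told apart from none, since the log2 ratio of OR counts to the geometric mean of 5 neuronal markers was higher by 0.92, with a pooled SD of 0.49. The markers were OMP, cnga4, gnal, ADCY3 and cngb1b, with 1 count added to each. Gallein replicate 2 held only 4 OMP, 2 cnga4 and 0 cngb1b counts, so the added count weighs on its ratio. Of the 10 splits of the 6 libraries, 1, the real split, gave a preset-correlation camera p as small as 7.3e-10, and the smallest other p was 2.8e-08. These 10 splits are too few for a share under 0.05. A preset-correlation camera p under 0.05 also came from 7 of the 9 other splits. Each of those mixes the groups unevenly and keeps part of the treatment difference, so it cannot show what arises without treatment. By size of the OR median the real split (-1.04) did not come first. The median was -1.40 with control replicates 1 and 3 grouped with gallein replicate 1, and -1.39 with gallein replicate 3 in its place. In all remaining splits it was smaller in size than in the real one. A shift of the real size can therefore also come from spread between libraries.

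That no gene passed in edgeR goes with a wide spread between samples of 1 group, for which differing cell makeup between sorts is a candidate explanation: 9 of 13 lists of other cell types varied within groups beyond the 95th percentile of 1000 random lists of like abundance. Any list of genes that move together can exceed random lists, and lists that mark no cell type were not put to this test. The pooled SD of the mean log2 level was 0.948 for ribosomal proteins and 0.683 for the mitochondrial genome, against 0.957 for skin and 0.664 for lens genes. It was lower for others, such as the unfolded protein response (0.233). The test therefore does not single out cell makeup. Variation arising after the spike-ins were added, in amplification and library preparation, could not be told apart from the rest over all counts. The spike-ins' median dispersion was 0.469 times that of genes of like mean count, and this ratio changed with the count. At 1000 or more counts it was 0.114 (0.0897 for spike-ins, 0.787 for genes). That value argues against such variation as the main source of spread for genes of that count. The ratio was 1.87 at 10 to 100 counts and 0.773 at 100 to 1000, which leaves the question open there. Of 6650 genes with a mean of at least 10 CPM, 485 (7.29%) had 1 library at 10 times the next or more, 162 of them in gallein replicate 2 and 135 in gallein replicate 1, while 0 of 37 spike-ins with a mean count of 100 or more did. All 10 splits of the libraries called 0 genes (highest other 0), too few splits for a share under 0.05.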

How the results depend on the processing

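All alternatives here were set before the data were examined except the ribosomal list without S6 kinases, which was chosen after seeing the data and kept its direction and preset-correlation call (median 1.25, adjusted p = 0.838 with an estimated correlation). The count of 0 genes held under 18 of 19 alternatives, and the DESeq2 Wald test called 93 (54 rose, 39 fell), 2 of them ORs. The OR median was negative under all 19, from -0.64 without gallein replicate 2 to -2.44 with spike-in size factors (-2.01 with the replicate block), and lost its preset-correlation call with at least 10 counts in every sample (-0.90, where fewer genes were tested) and with 1 factor from spike-ins (-1.07, cause not tested). With an estimated correlation the family's unadjusted p fell under 0.05 without the low-count filter (0.0343) and without gallein replicate 2 (0.0475). The number of called lists was 13 and became 8, 7 and 5 with at least 10 counts in every sample, 1 factor from control genes and 1 factor from spike-ins, and 6 to 15 with a replicate left out (6 without gallein replicate 2).

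Of 227 list values under the other settings, 166 kept the sign of the median and the call, 42 lost the call and 19 changed sign; OlfC receptors had too few genes with at least 10 counts in every sample. Camera's direction stayed in 12 of the 19, among them the 10 with spike-in size factors or library size only, which lower all genes (7 of these kept the call). With spike-in size factors the medians were -0.91 for ribosomal proteins, -1.48 for the respiratory chain, -1.09 for immediate early genes, -0.42 for erythroid, -1.20 for lens, -0.77 for myeloid and -0.75 for pigment genes. With 1 factor from spike-ins camera turned down for ribosomal proteins (-0.91, adjusted p = 0.000508) and the respiratory chain (-0.67, adjusted p = 0.00412), both called, and without a call for the lists at -1.76 (erythroid), -0.36 (lens), -0.29 (myeloid) and -0.61 (pigment). With library size only the medians were -0.10 (respiratory chain), -0.0487 (immediate early) and -0.14 (lens). With a replicate left out the medians ranged from -1.53 to 0.11 for photoreceptor (positive without control replicate 2), from -0.0196 to 2.102 for erythroid and from -0.26 to 1.604 for pigment genes (both negative without gallein replicate 2).

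Of 957 values of 52 named genes, 11 reversed, in 8 genes. With spike-in size factors EGR3 was at -0.37 and rac2 at -0.92, and with 1 factor from spike-ins hbae1.1 was at -3.06, MMP9 at -1.19, rac2 at -0.23 and TYRP1 at -3.37. With a replicate left out the values ranged from -3.06 to 0.0495 for GNG13, -0.35 to 5.41 for CRYBA1, -0.0474 to 5.28 for hbae1.1, -0.96 to 8.89 for TYRP1 and -0.22 to 5.47 for setdb1a, each reversed without the library with its highest level. In the DESeq2 Wald test 10 named genes passed, or70a12, or90a1, CNGA3 (ENSDARG00000012297), APOB, fth1a, KCNJ3 and the 4 picked from its calls. For the other reversals the cause was not tested.

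The replicate numbers showed no clear pairing of the samples (correlations of deviations 0.07, -0.12 and 0.18, against -0.25 to 0.18 for samples of unlike number). With so few replicates a pairing could not be excluded. With the replicate block 0 genes were called, the OR median was -2.01, and 14 lists were called with the preset correlation (the 13 and the cell cycle list, adjusted p = 0.0344). The summed OR level stayed at -1.16 (exact sign-flip p = 0.25, the smallest this pairing allows) and the number of OR genes detected at -21.

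In the simulation the spread limited recovery: with real dispersions 5% of simulated 16-fold changes were recovered, and with a dispersion of 0.05 at the same depth 100%. The changed genes were drawn only from those above a minimum mean count, and depth was not varied. Whether depth limits genes with few counts, as many OR genes have, was therefore not tested.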

Other observations

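The genes below were chosen after their values had been seen, and no explanation was tested for them. The DESeq2 Wald test called 93 genes, and in 61 of them the groups did not overlap. The gene ptgfrnb, a regulator of a prostaglandin receptor, had 185, 164 and 174 counts in the controls and 1, 1 and 0 in gallein (DESeq2 adjusted p = 0.000701, edgeR adjusted p = 0.756). LPAR6 (ENSDARG00000069441), a lysophosphatidic acid receptor gene, had 127, 34 and 84 counts in the controls and 0 in gallein (DESeq2 adjusted p = 0.00273). That puts it at least 48.4-fold lower, a bound that covers counting error only. The other gene named LPAR6 (ENSDARG00000062552) was at 4.30 ± 0.864 CPM in controls and 7.53 ± 2.51 CPM in gallein. HNF4G, a nuclear receptor gene, had 2, 0 and 0 counts in the controls and 46, 79 and 83 in gallein (DESeq2 adjusted p = 0.000824). SIRT5, a mitochondrial deacylase gene, had 70, 88 and 70 counts in the controls and 3100, 579 and 130 in gallein (DESeq2 adjusted p = 0.00143), so its gallein level differed widely between libraries. The edgeR test, which has the same counts, called none of these 4 genes, and in 6 of the 93 genes 1 library held over 90% of all counts.

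Markers of some tissues other than olfactory neurons had high levels in the libraries of both groups, and those of others did not. The mean log2(CPM + 1) of lens genes was 5.30 in controls and 5.86 in gallein, that of skeletal muscle genes 5.60 and 5.88 and that of skin genes 5.62 and 5.59, while that of brain genes was 3.17 and 3.21, of hair cell genes 2.88 and 2.85, of erythroid genes 1.82 and 2.41 and of myeloid genes 1.62 and 2.14, with 3.07 and 2.31 for genes of mature ciliated olfactory neurons. Crystallin genes took 0.626% of gene counts in controls and 0.692% in gallein, where the 93 OR genes took 0.0106% to 0.0144% in controls and 0.000696% to 0.00953% in gallein.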
